A study of Sus scrofa with 22 samples.

How the data were processed

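RNA from the distal small intestine of 22 piglets was labelled with Cy5 and hybridised together with a Cy3-labelled pool of all 22 RNAs, per the labels. All arrays have the same dye orientation, so a probe's dye bias is common to all groups and cancels in the comparisons between them. The series' value table holds 1 column per array. The deposited values are log2 ratios of piglet over pool: limma is named in the submitters' processing notes, with no version, and the base of the logarithm was taken as 2 because limma works on that scale. The direction of the ratio (Cy5 over Cy3) and the base are not stated in the table itself, so every signed value rests on the channels as the labels give them. Background correction and normalization within arrays are not given in the sources used here. The column medians of the tested probes lay between -0.03 and 0.01, and the values were used without further centring. Any 2 arrays correlated with an r between 0.268 and 0.910 across probes, and no 2 columns were identical.

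Of 20736 rows, 181 held no value and 659 held only 0 or missing values; these were left out, since no other row contained an exact 0. A probe was tested if it had a value on at least 4 arrays of each group, which left 18895 probes. The annotation table of the platform gives 1 gene symbol for 178 probes (175 symbols, 4 probes for ASIP and 1 for every other symbol), several symbols for 0 and none for 20558, which are unnamed here. The gene IDs of all 178 were found in the pig RefSeq table (assembly Sscrofa11.1), and 0 symbols changed. No array build is stated, so no coordinates are given. Gene-level values were the mean of a symbol's probes, and 170 symbols could be tested.

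Each of 6 contrasts was tested with limma (version 3.58.1, R 4.3.3): 1 linear model with 4 group means over all 22 arrays, moderated by empirical Bayes, 2-sided, with Benjamini-Hochberg adjustment over all probes (or all named genes) at a threshold of 0.05. The contrasts were high minus normal protein at 7 days and at 28 days, 28 minus 7 days over both diets and within each diet, and the interaction. Confidence intervals are at 95%. Piglets are separate animals. Weights were compared with exact 2-sided permutation tests within each age, adjusted over the 4 tests. The methods were tested on simulated data made from whole residual arrays in random order with 200 changed probes among 18895 and 20 repeats each. In the simulated age comparison a difference of 0.25 was recovered for 35.6% and one of 0.5 for 93.3% of changed probes. All 200 changed probes had 1 size, and the adjusted threshold eases as more probes change, so these shares hold for that setting only. The median number of false calls over repeats was at most 3.5, but a single repeat of the 7 day diet comparison reached 153. Whole arrays were moved, so probes kept any noise they share, but whether this caused the high count was not tested.

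Groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. For the 2 diet contrasts and the age contrast the rule took the genes of largest change among those past the threshold or, with fewer than 10 of them, the 10 of smallest unadjusted p. It took up to 4 genes from each list, or up to 2 where none passed, and the 10 of smallest unadjusted p for the interaction, and it left out symbols that are only a locus number. The probes given by number fall outside the rule and were chosen after their values were seen. Of 32 gene lists, 12 had a measured gene and 0 had the 5 genes needed for a set test, so no set test was run; list genes are reported as single genes.

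The labels give each piglet a pair number and a date of birth, and piglets that share both form 10 blocks with both diets in each. Piglets of 1 block were born on the same day, so these numbers were taken to pair the samples. Over the 13 array pairs of opposite diet within a block, deviations from the group means correlated with a mean r of 0.11 (from -0.30 to 0.58), against -0.02 for array pairs of other pair numbers. Alternatives were median centring, scaling to equal spread, quantile normalization, other limits on missing values, robust and trended empirical Bayes, array weights, sex or birth weight as a covariate, gene-level values, the pair as a fixed or random block, fits of only the groups compared, and leaving out each array. Added after seeing the data were centring of print blocks (48 equal stretches of consecutive probe numbers, taken as print blocks because placeholder rows recur at that interval), this together with array weights, and leaving out the arrays of pair 5 or the 3 arrays of lowest weight. Figures were drawn with matplotlib 3.10.9.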

Results

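Gene expression was measured in the distal small intestine of 22 piglets born with intrauterine growth restriction (low weight at birth after poor growth in the womb). The piglets received a high protein or a normal protein diet before weaning and were studied at 7 or 28 days of age. There were 6 piglets on each diet at 7 days and 5 on each diet at 28 days. RNA of each piglet was hybridised on its own 2-colour array against a common pool of the 22 RNAs, so every value is the log2 ratio of 1 piglet to the pool. Between 18813 and 19706 probes had a value on an array, and 18895 probes had enough values in each of the 4 groups to be tested. The number of arrays limits the precision. Only 178 probes carry a gene symbol in the platform annotation used here, and 170 symbols were tested, so most of what follows on named genes concerns a small part of the array.

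The listed weights did not separate the diets. At 7 days the listed weight at death was 1.402 ± 0.214 (SD, n = 6) with high protein and 1.37 ± 0.123 (SD, n = 6) with normal protein (exact permutation p = 0.786). At 28 days it was 5.30 ± 0.906 (SD, n = 5) and 4.90 ± 0.468 (SD, n = 5) (exact permutation p = 0.421). Weight at birth differed by -0.04 between the piglets later studied at 7 days and by 0.004 between those studied at 28 days (exact permutation p = 0.563 and 1). The labels state no unit for these weights, and all 4 Benjamini-Hochberg adjusted p were 1.

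The first comparison asked which transcripts differed between diets after 7 days. No named gene passed the test, and the genes nearest to it differed by less than 1.3-fold. ST3GAL4, a sialyltransferase that caps glycans with sialic acid, had a log2 difference of 0.36 ± 0.15 (SE) between high and normal protein piglets, the largest among the 10 genes of smallest unadjusted p. LY49, a receptor of natural killer cells, differed by 0.20 ± 0.093, and the milk protein gene CSN1S1 (alpha-S1-casein) by 0.20 ± 0.069. The other 7 had lower values with high protein. PMAIP1, which encodes the pro-apoptotic protein NOXA, differed by -0.29 ± 0.12. The urate oxidase gene UOX differed by -0.27 ± 0.12 and the somatostatin receptor gene SSTR5 by -0.22 ± 0.10. MMP14, a membrane-bound matrix metalloproteinase, differed by -0.20 ± 0.083 and FSHR, the receptor of follicle-stimulating hormone, by -0.19 ± 0.071. The odorant-binding protein gene OBP differed by -0.19 ± 0.070. PGLYRP2, which encodes a peptidoglycan-recognising enzyme, differed by -0.12 ± 0.053. The adjusted p of each of these 10 genes was 0.583 in limma's test. For 4 of them leaving out 1 array shrank the difference by more than 1.5-fold. Without normal protein 7 days replicate 5, LY49 differed by 0.11 and UOX by -0.15. ST3GAL4 differed by 0.22 without normal protein 7 days replicate 3, and SSTR5 by -0.13 without high protein 7 days replicate 5.

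Genes from the lists fixed in advance were few at 7 days, and none passed over all genes or adjusted over the list alone. All 4 measured antimicrobial genes had values below 0, among them the protegrin gene NPG4 at -0.33 ± 0.16 and PGLYRP2. The aspartate aminotransferase gene GOT1, the only measured gene of amino acid catabolism, differed by 0.23 ± 0.14. Without normal protein 7 days replicate 3, NPG4 was at -0.21 and GOT1 at 0.15. The peptide transporter gene SLC15A1, which takes up the di- and tripeptides of digested protein, differed by 0.00 ± 0.060, with a 95% confidence interval from -0.12 to 0.13. In apoptosis, FAS differed by 0.00 ± 0.11, beside PMAIP1. ATP5G1, a subunit gene of ATP synthase, differed by -0.16 ± 0.084. IL1A, the gene of the cytokine interleukin 1 alpha, differed by 0.10 ± 0.091, and by 0.04 without high protein 7 days replicate 5. Differences under 0.06 in size, with signs that are not read here, were seen for CD4 (-0.05 ± 0.092), the antigen-processing genes PSME1 (-0.06 ± 0.079) and PSMB8 (0.00 ± 0.083), the adaptor gene TYROBP of myeloid and natural killer cells (0.03 ± 0.088), the ghrelin gene GHRL (-0.03 ± 0.054) and the embryonic haemoglobin gene HBE1 (-0.04 ± 0.055). Over all 18895 probes limma called 0 at an adjusted p under 0.05, while 1653 had an unadjusted p under 0.05 against 945 set by chance. In simulations of this comparison, a difference of 0.5 was recovered for 79.0% of changed probes and one of 0.25 for 3.42%. The 200 changed probes of 1 size ease the adjusted threshold, so these shares do not carry over to data where few probes change. The measured diet differences at 7 days also followed the position of probes in the array's list. In the first of 48 equal stretches of probe numbers 86.5% of probes had a higher mean with high protein, with a median difference of 0.12, and medians in the 48 ran from -0.10 to 0.12. Of the 200 probes of smallest p, 23 lay in the first stretch, and 3 after every stretch was centred on each array. Centring lowered the 1653 to 1234. It left CSN1S1, whose probe lies in the first stretch, at 0.08, LY49 at 0.09, GOT1 at 0.11, IL1A at 0.05 and PGLYRP2 at -0.04, while NPG4 was at -0.44.

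The second comparison asked the same at 28 days. Again no named gene passed limma's test. Of the 10 genes of smallest unadjusted p, 8 had higher means with high protein, while over all 170 genes 79 were higher and 91 lower. QDPR, which encodes the reductase that regenerates tetrahydrobiopterin for the breakdown of phenylalanine, was at 0.39 ± 0.18 (SD, n = 5) with high protein and at -0.15 ± 0.11 (SD, n = 5) with normal protein. This was 1.46-fold higher, with no overlap between the diets, and the adjusted p was 0.206. The values of IL1A did not overlap either, at 0.41 ± 0.15 (SD, n = 5) against 0.11 ± 0.078 (SD, n = 5), with an adjusted p of 0.238. Both genes were picked for small p from these same values, so the lack of overlap is no separate support. The sperm tail gene ODF1 differed by 0.37 ± 0.12 (SE) and the oestrogen receptor gene ESR2 by 0.34 ± 0.11. CEND1, a gene of neuronal differentiation, differed by 0.26 ± 0.12 (0.16 without high protein 28 days replicate 3), TYROBP by 0.26 ± 0.096 and SSTR5 by 0.24 ± 0.11. TNFSF8, the gene of the CD30 ligand, differed by 0.16 ± 0.076. The tissue kallikrein gene KLK1 differed by -0.17 ± 0.071 and the sperm mitochondrial gene SMCP by -0.12 ± 0.060.

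QDPR was called when arrays were brought to equal spread or by quantile normalization (adjusted p = 0.0145 and 0.0155), with array weights (0.0277), in a fit of the 28 day piglets alone (0.0128), without normal protein 7 days replicate 3, and without the 3 arrays of lowest weight (0.0464). ODF1 and TYROBP passed with array weights (adjusted p = 0.0434 and 0.0277) and without those 3 arrays (0.0464 each). TYROBP also passed without normal protein 28 days replicate 4. The probes of QDPR, ODF1, TYROBP, IL1A and CEND1 all have numbers near the end of the array's list, where most probes read higher with high protein at 28 days. In the last of 48 equal stretches of probe numbers, 97.9% of probes had a higher mean with high protein, and their median difference was 0.22. Centring every stretch on each array left QDPR at 0.32, IL1A at 0.19, ODF1 at 0.17, CEND1 at 0.16 and TYROBP at 0.06, with adjusted p of at least 0.986. It also left ESR2 at 0.20, KLK1 at -0.10, NPG4 at 0.02 and PSMB8 at 0.00.

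Among the fixed lists at 28 days, IL1A for inflammatory signalling and TYROBP for myeloid cells were the only measured members of their lists, so that adjusted over the list alone their p values were 0.00559 and 0.0129, while over all genes neither passed. No other list had a member that passed. SLC15A1 differed by -0.05 ± 0.066 (SE), with a 95% confidence interval from -0.18 to 0.09, and GOT1 by -0.05 ± 0.15. Of the 4 antimicrobial genes 3 had higher values with high protein, by 0.16 ± 0.18 for NPG4 and 0.06 ± 0.082 for the beta-defensin gene DEFB1. GHRL differed by 0.09 ± 0.059, ATP5G1 by 0.12 ± 0.092, PSMB8 by 0.10 ± 0.091 and HBE1 by 0.03 ± 0.061. PSME1 was at -0.03 ± 0.086, CD4 at -0.02 ± 0.10, FAS at -0.07 ± 0.12 and PMAIP1 at -0.09 ± 0.14. Each of these 12 differences shrank by more than 1.5-fold or turned its sign when 1 array was left out. At the least NPG4 fell to 0.05, ATP5G1 to 0.05, DEFB1 to 0.02, GHRL to 0.05, PSMB8 to 0.07, HBE1 to 0.01, SLC15A1 to -0.03 and FAS to -0.02, and the sign turned for PSME1 (0.04), CD4 (0.05), GOT1 (0.04) and PMAIP1 (0.01). Over all probes limma called 0, with 987 at an unadjusted p under 0.05 against 945 set by chance. With array weights 26 probes were called, 25 of them higher with high protein, and 0 when the stretches of probe numbers were also centred. In simulations of this comparison, a difference of 0.5 was recovered for 72.3% of changed probes and one of 0.25 for 1.43%. The 200 changed probes of 1 size ease the adjusted threshold, so these shares do not carry over to data where few probes change. The real probe of smallest p, 20249, differed by 0.63 ± 0.12 (SE) with an adjusted p of 0.611 in limma's test.

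**Figure D1:**
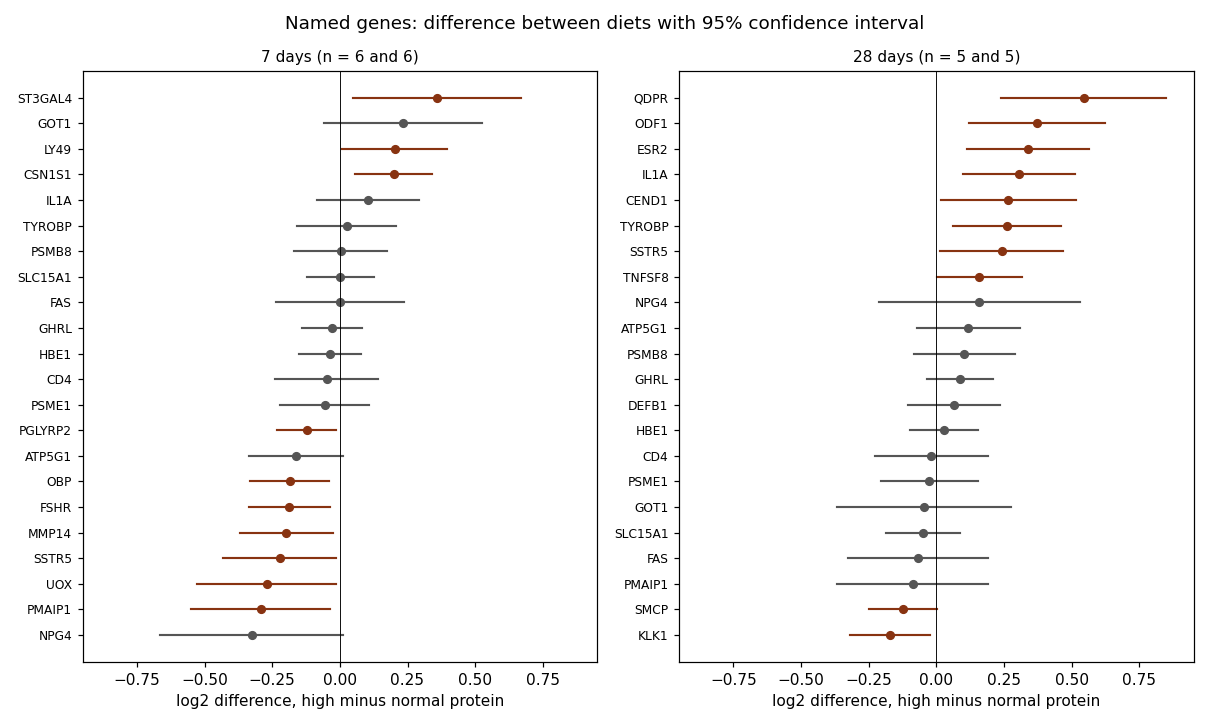
Log2 difference between high and normal protein piglets for the named genes at 7 days (left) and 28 days (right); points are fitted differences, bars their 95% confidence intervals, and red marks the 10 genes of smallest unadjusted p. At 28 days QDPR lies farthest from 0, at 0.54, and no gene passed the adjusted test at either age.

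The third comparison followed the intestine from 7 to 28 days over both diets. Here 17 probes passed limma's test, 9 higher and 8 lower at 28 days, and all 17 had the same direction in both diets. The 17 were picked for the mean of the 2 diets, which favours equal directions beforehand, so this is no separate support. None of them carries a gene symbol. Probe 12328 rose by 0.93 ± 0.12 (SE) on the log2 scale, or 1.90-fold (adjusted p = 0.00102), and its values at 28 days all lay above those at 7 days. Only 2 of the 17 probes lacked overlap between the ages. As they were picked from these same values, this is no separate support. Probe 12328 stood at -0.87 ± 0.36 (SD, n = 6) in normal protein and -0.78 ± 0.29 (SD, n = 6) in high protein piglets at 7 days. At 28 days it stood at 0.26 ± 0.30 (SD, n = 5) and -0.05 ± 0.25 (SD, n = 5). Probe 17990 rose by 0.54 ± 0.077 (SE; adjusted p = 0.00302). Probe 20100 fell by 0.53 ± 0.10 (SE; adjusted p = 0.0445) and probe 2275 fell by 0.38 ± 0.064 (SE; adjusted p = 0.0168). These are the 2 largest rises and the 2 largest falls among the 17. Probe 20100 was close to the threshold: it missed it with sex (adjusted p = 0.101) or birth weight (0.0695) as a covariate and without any of 13 of the 22 arrays (up to 0.113). Probe 2275 missed it with sex as a covariate (0.0716) and without high protein 28 days replicate 2 or normal protein 28 days replicate 3. Age and sex were not balanced, since 9 of the 12 younger and 4 of the 10 older piglets were male. With sex as a covariate 4 of the 17 stayed called, but the 17 kept between 87.7% and 111% of their size, while the standard error was a median of 1.08 times as large.

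**Figure D2:**
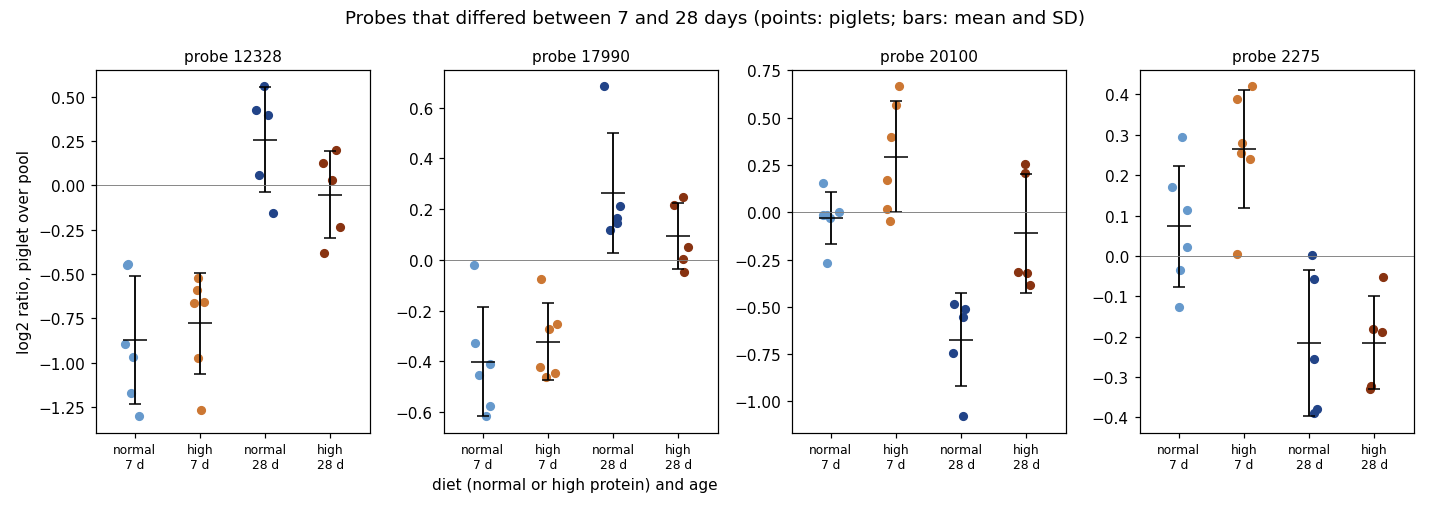
Log2 ratio of each piglet to the pool for the 2 probes that rose most and the 2 that fell most between 7 and 28 days, by diet and age; points are piglets, and bars show the mean and SD of 5 or 6 piglets. The values of probe 12328 at 28 days lie above all values at 7 days in both diets, but the probe was picked from these same values.

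Among named genes none passed the age test. The gene nearest to it was SHAS2, with a log2 difference of 0.20 ± 0.048 (SE) between 28 and 7 days and an adjusted p of 0.073. The death receptor gene FAS differed by 0.29 ± 0.085 (adjusted p = 0.117), and adjusted over the list alone its p was 0.00412 among the 2 measured apoptosis genes. UTS2, the gene of the vasoactive peptide urotensin 2, differed by 0.16 ± 0.046. The glutamate decarboxylase gene GAD2 differed by 0.18 ± 0.059, the melanosome gene OCA2 by 0.19 ± 0.065, the sperm phospholipase gene PLCZ1 by 0.18 ± 0.061 and the milk protein gene LALBA (alpha-lactalbumin) by 0.15 ± 0.052. Lower means at 28 days were found for QDPR (-0.33 ± 0.10), for SCAMP1 (-0.24 ± 0.077), a gene of secretory vesicle membranes, and for the oxytocin receptor gene OXTR (-0.21 ± 0.074). SHAS2 passed after quantile normalization (adjusted p = 0.0407), and 5 named genes passed with array weights (adjusted p from 0.0212 to 0.0485). These were SHAS2, FAS, QDPR, SCAMP1 and the inhibin alpha gene INHA, which is given here because of that call and had the smallest adjusted p, with a log2 difference of -0.28 ± 0.060 in that fit. With the stretches of probe numbers centred as well, 0 named genes passed, and each of these 5 had an adjusted p of 0.0851. SHAS2, FAS and QDPR also passed without normal protein 7 days replicate 3, and SHAS2 without high protein 7 days replicate 1 or normal protein 7 days replicate 6. Of the genes in the other lists, PSME1 differed by 0.14 ± 0.058, CD4 by 0.09 ± 0.068, GOT1 by -0.14 ± 0.10 and NPG4 by -0.13 ± 0.12. NPG4 was at -0.07 without normal protein 7 days replicate 3, and PSME1 at 0.09 without high protein 28 days replicate 5. The differences of DEFB1 (0.04 ± 0.056), GHRL (-0.05 ± 0.040), ATP5G1 (0.03 ± 0.062), HBE1 (-0.03 ± 0.041), PSMB8 (-0.03 ± 0.062), SLC15A1 (-0.02 ± 0.044), IL1A (-0.07 ± 0.068), TYROBP (-0.04 ± 0.065) and PMAIP1 (-0.01 ± 0.092) were each within 0.08 of 0, and their signs are not read here.

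The number of age-related probes depended on how the noisiest arrays were treated. It was 1386 with array weights (471 higher, 915 lower) and 151 without the 2 arrays of the pair numbered 5. The 17 probes called above were among those called in both. After scaling to equal spread 33 probes were called, 13 higher and 20 lower at 28 days. Without single arrays the count ran from 2 (without high protein 28 days replicate 2 or normal protein 28 days replicate 3) to 206 (without normal protein 28 days replicate 4).

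Within each diet, 16 probes differed with age in normal protein piglets (3 higher, 13 lower at 28 days) and 0 in high protein piglets. At an unadjusted p under 0.05 there were 3616 and 793. Quantile normalization gave 4 probes in normal protein piglets (3 higher, 1 lower) and scaling to equal spread gave 22 (8 higher, 14 lower). Without the arrays of pair 5 the counts were 1054 and 0, and a fit of the normal protein piglets alone called 0. None of the 16 probes carries a gene symbol. Of the named genes in normal protein piglets, QDPR was among those nearest to the threshold, at 0.44 ± 0.39 (SD, n = 6) at 7 days and -0.15 ± 0.11 (SD, n = 5) at 28 days (adjusted p = 0.0536). QDPR passed in 12 of 37 alternative fits, among them scaling to equal spread (adjusted p = 0.0117), quantile normalization (0.0211) and array weights (0.0121), and 6 of the 22 in which 1 array was left out. It did not pass with sex or birth weight as a covariate or in a fit of these piglets alone (adjusted p = 0.160). SSTR5 passed in 8 of the 37, GAD2 in 4, KLK1 in 3, and ODF1 and TYROBP in 1 each. The probe of QDPR lies in the last stretch of probe numbers, whose median difference here was -0.15. Centring the stretches left QDPR at -0.45 (adjusted p = 0.111), and with array weights as well at -0.39 (adjusted p = 0.0463). In high protein piglets QDPR was at 0.46 ± 0.19 (SD, n = 6) and 0.39 ± 0.18 (SD, n = 5) at these ages (adjusted p = 0.957). The direct test of whether the diet difference changed with age, an interaction, called 0 probes in limma, with 1186 at an unadjusted p under 0.05.

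No named gene passed the interaction test either. SSTR5 had the smallest p: its diet difference was higher at 28 than at 7 days by 0.46 ± 0.15 (SE) on the log2 scale, going from -0.22 to 0.24. QDPR followed the same direction by 0.53 ± 0.20, UOX by 0.45 ± 0.18, ODF1 by 0.39 ± 0.16 and ATP5G1 by 0.28 ± 0.12. The diet difference was lower at 28 than at 7 days for HRH4, a histamine receptor gene (-0.46 ± 0.22), for KLK1 (-0.28 ± 0.096), GAD2 (-0.27 ± 0.12), CSN1S1 (-0.24 ± 0.10) and the interferon beta gene IFNB1 (-0.22 ± 0.097). The adjusted p was 0.743 for HRH4 and 0.654 for the other 9. Centring the stretches of probe numbers left CSN1S1 and IFNB1 at -0.14 each.

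**Figure D3:**
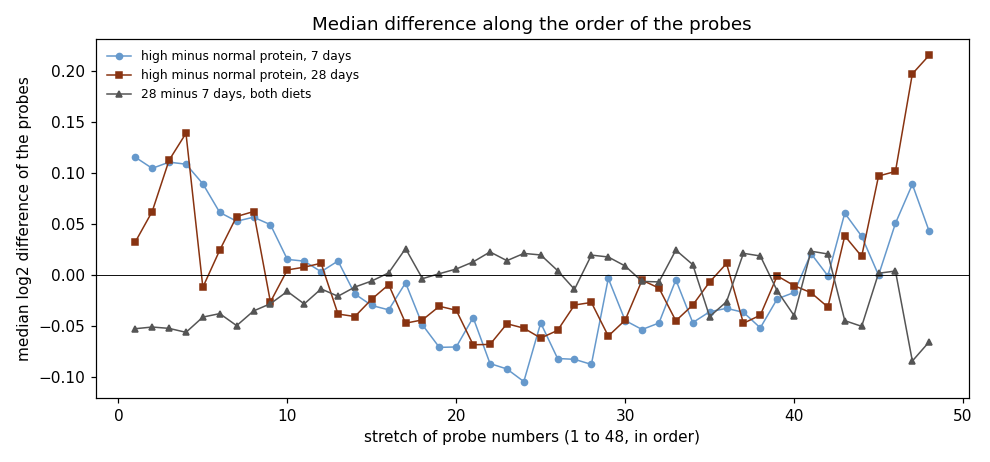
Median log2 difference of the probes in each of 48 equal stretches of probe numbers, for diet at 7 days, diet at 28 days and age over both diets. The last stretch reaches 0.22 for diet at 28 days and the first 0.12 for diet at 7 days. The medians for age also vary along the order, from -0.08 in stretch 47 to 0.03.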

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

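Tests of print blocks, of arrays left out together and of sizes with sex in the model were chosen after the results were seen. Outlying arrays were searched in 192 groups of values (48 measures in 4 groups). In 15 of them 1 array stood far from the others, against 9.6 by chance at 1 in 20. Normal protein 7 days replicate 5 accounted for 6 of the 15. Its log2 ratios had the widest spread (SD 0.526 against 0.293 to 0.366 in its group), and it stood apart in CSN1S1 (-0.41), UOX (1.05), LY49 (-0.59), SLC15A1 (-0.13) and KLK1 (-0.70). High protein 7 days replicate 1 had a narrow spread (SD 0.275 against 0.333 to 0.353). In normal protein 28 days piglets, replicate 1 stood apart in ST3GAL4 (-0.20) and CD4 (-0.51), replicate 2 in SMCP (-0.10) and in listed birth weight (1.12 against 0.82 to 0.88), and replicate 5 in probe 17990 (0.68). In high protein 28 days piglets the outlying values were SMCP in replicate 4 (0.0051), SCAMP1 in replicate 3 (0.29) and OXTR in replicate 5 (-0.29).

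Diet differences at 28 days gathered at the end of the probe order: 90 of the 200 probes of smallest p lay in the last 2 of 48 print blocks, where 8.38 would lie by chance. After centring each block on each array, 12 did. Centring removes a shift shared by a block whatever its cause, so this fall cannot tell uneven signal over the array surface from other causes. A diet response of single genes printed there was predicted to keep most of the 90 probes among the 200 after centring, but only 9 stayed. These probes had been picked with the shift of their block included, so their loss does not argue against such a response. The 26 probes called with array weights could also arise by chance, since 8 of 100 splits of the 28 day piglets gave as many and the highest other count was 368, which points to a structure of the samples or to noise shared between the probes of an array; which of them was not tested. Uneven signal over the array surface and a response of the genes printed in these blocks both stay open.

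Few probes passed the age test although 3062 had an unadjusted p under 0.05. Without the 3 arrays of lowest weight (normal protein 7 days replicate 5 and the 2 arrays of pair 5) 369 passed. Of the 150 ways to leave out 3 arrays of the same groups, only this one gave as many (highest other 356). A low weight marks large deviations in this same model, so that rank was favoured beforehand. Left out singly, normal protein 7 days replicate 5 gave 30. The 2 arrays of pair 5 gave 206 (normal protein 28 days replicate 4) and 5 (high protein 28 days replicate 5). Deviations of these 2 correlated with an r of 0.58, so they stood apart together. Whether the wide spread of the 3 arrays hides age differences stays open. Centring print blocks gave 37 with all arrays and 86 without the 3, where 2 of the 150 gave as many (highest other 86). Shifts of whole blocks, whatever their cause, can thus account for much of the 369 but not for the whole rise. Of 100 splits of ages within diet, 1, the real one, gave 17 or more probes, and the highest other gave 0. Without pair 5, 1 of 100 gave 151 or more (highest other 4). With array weights 1 of 100 gave 1386 or more (highest other 865). A random order of single piglets thus rarely gave such counts. Splits of whole pairs were not run, so chance differences between pairs are not excluded. With sex as a covariate 4 of the 17 were called. The 13 others went from a median size of 0.30 ± 0.059 (SE) to 0.29 ± 0.064, so their calls ended with wider errors and little change in size. This argues against sex, as labelled, as the source of these differences. Each pair lies within 1 age, so differences between pairs stay open beside age.

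More probes differed with age in normal than in high protein piglets, by 2823 at an unadjusted p under 0.05. Of 100 random assignments of diet within age, 8 gave a gap as large (highest other 3404), so chance could not be excluded. By calls, 9 of 100 gave a gap of 16 or more. These assignments moved diet across blocks of pair and birth date, and assignments within blocks were not run for the gap. The gap was 3379 after centring print blocks, which argues against shifts of whole blocks as its source. Uneven signal within a block is not removed by centring and was not tested. The calls themselves changed: centring again gave 16 in normal protein piglets, but only 7 were among the 16 called without it. Of the 200 probes of smallest p in these piglets, 25 lay in the last 2 blocks, and 8 after centring. The 200 probes of smallest p in normal protein piglets kept 13.3% of their median size in high protein piglets, and the 200 picked in high protein piglets kept 50.99% of theirs in normal protein piglets. The mark set for a weaker age change with high protein was a second share of 100%, and for equal changes shares within 10 points of each other. Neither was met. Picking probes by small p inflates their size where they were picked, so both shares are biased downwards and 100% was hard to reach. A weaker change and an equal one could therefore not be told apart by this test.

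For the other comparisons the splits were as follows, and chance could not be excluded in any of them. As many probes at an unadjusted p under 0.05 came in 14 of 100 splits for diet at 7 days (real 1653, highest other 2827), in 44 of 100 for diet at 28 days (987, highest other 4085), in 32 of 100 for age in high protein piglets (793, highest other 3899) and in 23 of 100 for the interaction (1186, highest other 3026). Among splits that part every block of pair and birth date, 4 of 32 at 7 days (highest other 2326) and 5 of 24 at 28 days (highest other 2133) gave as many. For age in normal protein piglets, 4 of 100 splits, the real one included, gave 16 or more called probes, just under the limit of 5 set beforehand. However, 1 of the others gave 205, which points to a structure of the samples or to noise shared between the probes of an array. Which of them was not tested. A fit of these piglets alone called 0, and the splits moved single piglets although each pair lies within 1 age. Chance therefore stays possible here.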

How the results depend on the processing

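Print-block centring and the removal of pair 5 or of 3 arrays were chosen after seeing the data; the cause of the changes was not tested unless stated. Diet at 7 days gave 0 probes under every alternative, and diet at 28 days gave 0 except with array weights (26), without pair 5 (2) and without the 3 arrays of lowest weight (3). Leaving out single arrays gave 0 for diet at 7 days and 0 to 9 at 28 days (9 without normal protein 28 days replicate 4). The interaction gave 0 to 1 (1 without that array) and 0 elsewhere. For age over both diets the 17 calls became 33 after scaling to equal spread, 1386 with array weights, 4 with sex and 5 with birth weight as a covariate, 37 after print-block centring, 932 with that and array weights, 151 without pair 5, 369 without the 3 arrays, and 0 among gene-level values, where only 170 genes were tested. Without single arrays they ran from 2 to 206. In normal protein piglets at 28 days these were 10, 6, 2, 206 without replicates 1, 2, 3, 4; in high protein piglets at 28 days 6, 2, 60, 5, 5 without replicates 1 to 5; in normal protein piglets at 7 days 4, 8, 6, 9, 30 without replicates 1 to 5; and in high protein piglets at 7 days 5, 9, 4, 40, 8 without replicates 2 to 6.

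For age in normal protein piglets the 16 calls became 4 after quantile normalization, 2 with robust and trended empirical Bayes, 1649 with array weights, 2 with sex and 7 with birth weight as a covariate, 0 in a fit of these piglets alone (fewer arrays), 1054 without pair 5, 1003 without the 3 arrays, 1244 with print-block centring and array weights, and 0 among gene-level values. Without single arrays they ran from 0 to 902: at 28 days 5, 2, 0, 902, 0 without normal protein replicates 1 to 5, at 7 days 0, 25, 1, 98, 2, 34 without normal protein replicates 1 to 6, 138 without high protein 7 days replicate 5 and 33 without high protein 28 days replicate 5. In high protein piglets 0 became 1 with array weights and 6 with print-block centring and array weights, and stayed 0 with each single array left out.

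With the pair, or pair and birth date, as a replicate block both diet effects stayed at 0, with 1549 and 2308 probes at an unadjusted p under 0.05 at 7 days and 1106 and 1292 at 28 days. With the pair as a random block (correlation -0.01) the age counts were 23 over both diets and 19 in normal protein piglets. This block was the pair number alone, which can join piglets of different birth dates. A random block of pair and birth date was not run for age, so its effect on these counts was not tested. The block changed no call of weights, whose exact permutation p within blocks were 0.469 and 0.781 at 7 days and 1 and 0.292 at 28 days. The 77 differences given for named genes kept their sign and side of the threshold in 2805 of 2899 alternatives. In 21 they passed the threshold, and in 73 they changed sign without passing it. No named gene passed in the main fit, so keeping the side means only that a gene again did not pass. Leaving out an array of the other age could not change the sign of a diet difference. Part of this agreement was therefore fixed beforehand, and the count is no measure of robustness. The 4 age probes kept their direction in all 144 and missed the threshold in 18. The set tests planned for gene lists were not run, because 0 lists had 5 measured genes. Signal over background is not in the values used here, so dim probes could not be told from bright ones.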

Other observations

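The tests of sex and of splits for named genes were chosen after the results were seen; the test of genes of other tissues was not, although differences of some of its genes had been. With age and diet in the model, 1 unnamed probe differed between sexes in limma's test (adjusted p = 0.00164), with 451 probes at an unadjusted p under 0.05. This probe, 9480, was chosen after its values were seen. It was higher in the 9 females (0.36 ± 0.23, SD) than in the 13 males (-0.30 ± 0.17, SD), a difference of 0.67 ± 0.085 (SE) or 1.59-fold. All 9 females (0.13 to 0.94) lay above all 13 males (-0.61 to -0.04). As the probe was picked for its sex difference out of 18895, this separation does not check the sex in the labels. SRY, the Y-linked gene that should be expressed in males only, did not pass limma's test: its male minus female difference was -0.03 ± 0.12 (SE; adjusted p = 1.00). Its probe had a mean of 0.574 in piglets labelled female and 0.602 in those labelled male, so it did not separate the labelled sexes. SRY is among the 26 genes known mainly from other tissues, so its probe may have read no transcript here. Its lack of difference therefore does not bear on the labels. The adjusted p of probe 9480 covers all probes tested, so the labelled sexes differed in this probe. A single unnamed probe picked from the array does not check each piglet, so the sex of single piglets stays unchecked. SRY also had the largest difference of the 26 genes of other tissues, given below, for diet at 7 days and for age.

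The named genes include 26 known mainly from other tissues, such as the sperm genes PRM1, ODF1 and SMCP, the casein gene CSN1S1, the retinal gene ARR3 and the enamel gene MMP20. If the differences of the named genes were technical, these should spread as widely as the rest. For diet at 28 days the root mean square log2 difference was 0.12 in these 26 and 0.11 in the other 144 named genes, a ratio of 1.08 (permutation p = 0.723 for a smaller spread), and for age it was 0.10 in both (ratio 0.977, permutation p = 0.472). For diet at 28 days, 1 of the 26 and 8 of the 144 had an unadjusted p under 0.05, in all 9 of 170, and 41 of 100 splits of the 28 day piglets gave as many (highest other 34), so chance could not be excluded. For age, 7 of the 26 and 22 of the 144 did, in all 29 of 170. Of 100 splits of ages within diet 2 gave as many, the real one included, and the other gave 43. A random order of single piglets thus rarely gave as many. Splits of whole pairs were not run, so chance differences between pairs are not excluded. As the listed genes took part, the values do not tell an age difference in the tissue from one between arrays of the 2 ages. The levels of these 26 transcripts in the intestine were not measured, so expression of some of them there stays open.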
